A study of Mus musculus with 9 samples.

How the data were processed

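RNA from mouse tumour tissue, recorded under the tissue name MB, was profiled by bulk RNA sequencing at postnatal day 8 or 9. The 9 libraries form 3 groups of 3. SG carries the conditional SMO-M2 allele and the hGFAPcre driver. YSGr and YSGnr carry these together with a floxed Yap1 allele and are marked in the labels as rescued and non-rescued. The labels do not define rescue, do not give the sex of the animals, and do not say whether each library came from a separate animal, so p-values measure the spread between libraries, which may in part be technical.

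Per the labels' protocols, RNA was extracted with a Trizol-type reagent and total RNA was sent to BGI for library preparation and sequencing on the DNBseq platform. How ribosomal RNA was removed and whether libraries kept strand are not given in the sources used here. The authors' processing notes name Trimmomatic, RSEM, Bowtie2, Picard and edgeR and the mouse build mm10, with no versions. The annotation version is not given in the sources used here. The authors deposited 1 table of log2 CPM (CPM, read counts scaled to library size) for 17482 genes in the 9 libraries. The values already carry a library scaling and an added count made by the authors. Every library reaches the same lowest value, -3.52, and the added count this implies averages 2.00 reads over the libraries, the default form of the log CPM that the authors' named tool edgeR makes. From it the effective library sizes came to between 18.1 and 32.3 M (mega) reads in 8 libraries and to 3.92 M reads in YSGnr replicate 1. Between 45.9% and 70.1% of the back-calculated values were whole to within 0.02 reads, so the counts were estimated rather than whole and no count test was the main test. A fold change on this scale understates the change of genes near the lowest value.

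Group differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 CPM, with a group-means model over all 9 libraries, a mean-variance trend and a two-sided moderated test. Genes entered with a log2 CPM above 0 in at least 3 of the 9 libraries, which left 15251. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over these genes. Gene lists were compared with all other tested genes by camera with a preset correlation of 0.01, adjusted over the 33 of 35 lists with at least 3 tested members, and again with a correlation estimated for each list. The fry test, which asks whether a list's genes move on balance one way and does not compare them with other genes, was a further alternative. The lists, the tests, the main alternatives and the rule for named genes were fixed before the data were examined. The rule names Yap1 and the sex-linked genes Xist, Ddx3y, Kdm5d, Uty and Eif2s3y. It names, per comparison, the 10 largest positive and 10 largest negative log2 fold changes among called genes with a mean log2 CPM of at least 1 in the higher group and no overlap between the groups' libraries, leaving out predicted-gene symbols, immune receptor segments and the sex-linked genes. It names per list up to 4 called members, or up to 2 members as values only where none was called. Genes named outside the rule are marked as chosen after their values were seen.

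On simulated data with 200 changed genes among 15251, the same steps recovered 43% of genes changed by 1 log2 unit and 83% of those changed by 2 for YSGr against SG, 31% and 75% for YSGnr against SG, and 33% and 84% for YSGr against YSGnr, with 11, 3 and 5 false calls. The simulated noise was independent between genes and equally wide in every library of a gene. The real libraries spread unequally, so these rates need not hold for them.

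Alternatives were no filter, a stricter filter at a log2 CPM above 1, a pseudocount of 1, median scaling, quantile normalization, the 6 libraries of a comparison alone, no trend, robust empirical Bayes, array weights, the replicate number as a block, and each library left out in turn. Added after seeing the data were the removal of a transcript length and GC trend from each library, the omission of YSGr replicate 3 with YSGnr replicate 1, the omission of YSGnr replicate 1 with the trend removed, limma voom on back-calculated reads, and the block with the trend removed. Lengths, GC and coordinates came from GENCODE M21 on GRCm38, the assembly of mm10, where 95.6% of the symbols matched a single gene. Replicate libraries differed by more than sampling noise in every pair, with a median chi-square per gene of at least 1.40 where sampling alone gives 0.45, so none was merged.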

Results

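Gene expression was measured in 9 libraries of mouse tumour tissue driven by SMO-M2, a constitutively active form of the Hedgehog receptor component Smoothened, under an hGFAPcre driver. SG tumours (n = 3) carried no floxed Yap1 allele, and the rescued YSGr (n = 3) and non-rescued YSGnr (n = 3) tumours carried one. Yap1 encodes the transcriptional coactivator of the Hippo pathway. The series title places the samples in a study of sex differences in the function of Yap1 in immune evasion. Back-calculated reads summed to between 17.3 and 29.2 M in 8 libraries and to 9.66 M in YSGnr replicate 1, with 3.53 M of these outside Yam1 and Lars2, so low genes are measured least precisely there. In that library Yam1 and Lars2, chosen after their values were seen, together took 63.4% of the reads, against 1.98% to 8.15% in the other 8, and the median of 38 histone genes was 5.87 log2 CPM, against at most 2.07.

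Yap1 (ENSMUSG00000053110.13, chromosome 9, 7931999 to 8004596, GRCm38) was reported first, as the targeted gene. Its level was 5.06 ± 0.05 log2 CPM in SG, 3.51 ± 0.84 in YSGr and 2.45 ± 0.41 in YSGnr (SD, n = 3 each). The YSGr libraries stood at 4.44, 3.31 and 2.79 and the YSGnr libraries at 2.79, 2.57 and 1.99, all below the 3 SG libraries. Yap1 fell by 1.55 on the log2 scale in YSGr (SE 0.38, adjusted p = 0.0327) and fell by 2.61 in YSGnr (SE 0.38, adjusted p = 0.0131). The difference between YSGr and YSGnr, 1.06 log2 units (SE 0.38), was not called (adjusted p = 0.0959). Gene-level values cannot separate reads over deleted exons from reads over the others. The call in YSGr was lost without SG replicate 1, 2 or 3, YSGr replicate 2 or YSGnr replicate 2 (adjusted p = 0.112, 0.114, 0.1, 0.125 and 0.0513). The call in YSGnr was lost without SG replicate 1, 2 or 3 or YSGnr replicate 3 (adjusted p = 0.0955, 0.0834, 0.0785 and 0.0577). Without YSGr replicate 3 the difference between YSGr and YSGnr was called, at 1.42 log2 units (adjusted p = 0.00983). Without YSGr replicate 1, the highest of its group, the difference was 0.60 and was not called (limma, adjusted p = 0.286). Nor was it called with the 6 libraries of these groups alone (limma, adjusted p = 0.223).

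**Figure D1:**
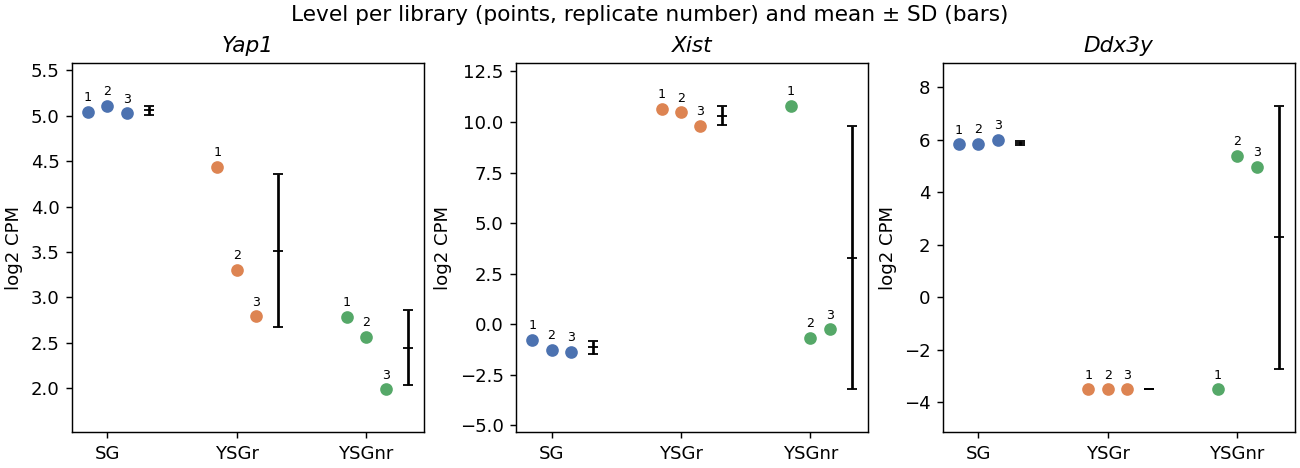
Levels of Yap1, Xist and Ddx3y in log2 CPM for each library, with points numbered by replicate and bars giving the mean ± SD of 3 libraries per group. Yap1 averaged 5.06 in SG, 3.51 in YSGr and 2.45 in YSGnr, and YSGnr replicate 1 stood with the YSGr libraries for Xist and Ddx3y.

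Transcripts of the sex chromosomes separated the YSGr libraries from the SG libraries and divided the YSGnr libraries. Xist, the RNA that coats the inactive X chromosome, stood at 10.66, 10.48 and 9.81 log2 CPM in YSGr and at 10.81 in YSGnr replicate 1, and between -1.38 and -0.25 in the SG libraries and YSGnr replicates 2 and 3. The Y-linked helicase gene Ddx3y and demethylase gene Kdm5d were at the lowest value of the table, -3.52, in the 3 YSGr libraries and YSGnr replicate 1. Ddx3y averaged 5.88 ± 0.09 and Kdm5d 5.18 ± 0.11 in SG (SD, n = 3). Uty averaged 4.50 ± 0.20 in SG and -1.23 ± 0.67 in YSGr, and Eif2s3y 5.84 ± 0.09 and -3.34 ± 0.30. All SG libraries therefore had high Y-linked transcripts and all YSGr libraries high Xist, and no comparison of these groups holds libraries alike in these transcripts.

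The comparison of YSGr with SG asks how tumours with the floxed Yap1 allele that were marked as rescued differ from tumours without that allele. Of 20 markers of mature cerebellar granule neurons 11 rose in YSGr, including Gabrd, a GABA receptor subunit, which was 10.7-fold higher (log2 fold change 3.42, SE 0.26, adjusted p = 0.000582), and Cbln3, a cerebellin gene, with a log2 fold change of 3.32 (SE 0.18, adjusted p = 9.19e-05). Of 12 myelin genes 9 rose and of 12 Purkinje cell markers 4 rose. Of 30 cell cycle genes 8 fell, of 16 Hedgehog pathway genes 4 and of 12 neural stem cell genes 3. Camera called these 6 lists with a preset correlation and none with an estimated correlation, where the adjusted p lay between 0.224 and 0.593. In all, 1003 genes were higher and 605 lower in YSGr among 15251 tested (limma), and 569 and 258 of these differed by at least 2-fold. The groups did not overlap at 36.8% of the tested genes, against 10% by chance.

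Of the 20 granule neuron markers none fell and 9 were not called, and 16 rose when adjusted over the list alone. The GABA receptor subunit gene Gabra6 was 8.34-fold higher (adjusted p = 0.000734), and Slc17a7, a vesicular glutamate transporter gene, 7.69-fold higher (adjusted p = 0.00204). Of 12 myelin genes 9 rose, or 11 adjusted over the list alone, among them Opalin (7.55-fold, adjusted p = 0.0176), Mog (5.18-fold, adjusted p = 0.0193) and Mag (4.56-fold, adjusted p = 0.0068). Of 12 Purkinje cell markers 4 rose, or 8 adjusted over the list alone: Ppp1r17 by 2.82 log2 units (SE 0.32), Slc1a6 by 1.72 (SE 0.13), Pcp4 by 1.45 (SE 0.15) and Pcp2 by 1.41 (SE 0.15). Camera called the 3 lists at adjusted p = 7.84e-13, 2.57e-08 and 3.54e-08. With an estimated correlation the adjusted p was 0.471 for the granule neuron list, 0.487 for the myelin list and 0.471 for the Purkinje list. Libraries differed within the group, and the granule neuron median stood 1.55 and 1.53 log2 units above SG in YSGr replicates 1 and 2 and 0.72 in replicate 3.

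Of 30 cell cycle genes 8 fell and 22 were not called, and 10 fell adjusted over the list alone. Mki67, a marker of dividing cells, averaged 9.82 ± 0.05 log2 CPM in SG and 8.79 ± 0.27 in YSGr (SD, n = 3) and fell by 1.02 (SE 0.19, adjusted p = 0.0141), and the kinetochore motor gene Cenpe fell by 1.00 (SE 0.16, adjusted p = 0.00722). Of 16 Hedgehog pathway genes 4 fell, or 8 fell and 1 rose adjusted over the list alone. Hhip, a Hedgehog binding protein gene, fell by 2.37 (SE 0.44, adjusted p = 0.0136), the cyclin gene Ccnd1 fell by 2.03 (SE 0.52, adjusted p = 0.0385) and the receptor gene Ptch1 fell by 1.83 (SE 0.41, adjusted p = 0.0244). The adjusted p of the lists was 7.23e-10 for the cell cycle and 0.00127 for Hedgehog, and 0.593 for both with an estimated correlation. By fry neither was called (adjusted p = 0.0776 and 0.0908). Relative to SG the median of the cell cycle list was -0.90 and -1.22 in YSGr replicates 1 and 2 and 0.04 in replicate 3, and the Hedgehog median was -1.15, -1.40 and -0.04.

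Of 12 neural stem cell genes 3 fell, or 8 adjusted over the list alone: the intermediate filament gene Nes (log2 fold change -1.49, SE 0.29), the transcription factor gene Sox2 (-0.91, SE 0.17) and the Notch target Hes5 (-0.88, SE 0.22). Of 15 Hippo pathway core genes 3 fell, or 4 adjusted over the list alone: Wwc1 (log2 fold change -1.05, SE 0.21), Tead1, a DNA-binding partner of YAP (-0.96, SE 0.21), and Wwtr1, the gene of the YAP paralog TAZ (-0.65, SE 0.14). These lists were called at adjusted p = 0.00254 and 0.00104, and at adjusted p = 0.224 for both with an estimated correlation. The YAP and TEAD target list was not called by camera (adjusted p = 0.797) or by fry (adjusted p = 0.663): of 22 genes Myof and Gadd45a were among 3 that rose, Ajuba and Asap1 fell, and 17 were not called. Of 7 erythrocyte genes 3 fell, 1 rose and 3 were not called. Those that fell were the heme synthesis gene Alas2 (log2 fold change -1.25, SE 0.24) and the globin genes Hba-a1 (-1.17) and Hbb-bs (-0.99). The list was called at adjusted p = 0.0352, and at adjusted p = 0.567 with an estimated correlation. Globin genes have near-identical copies and their values are uncertain.

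Beyond the lists, Fam107a (17.2-fold), Mybpc3 (12.3-fold), Trp73, a p53 family gene (11.5-fold), Galnt15 (9.36-fold), Ly6d (8.09-fold) and Plac9b (7.11-fold) were among the 10 largest increases that the naming rule admits. Among the largest decreases were the transcription factor genes Olig3, which fell by 4.06 (SE 0.38, adjusted p = 0.000998), Shox2 (log2 fold change -4.57, SE 0.99) and Pitx3 (-4.38, SE 0.68). Gpr50 (-4.53, SE 1.08), Myog (-4.01), Igf2bp1 (-3.85) and Prm1 (-3.84) were also among them, with Myog at the lowest value of the table in 2 of the 3 YSGr libraries. The pseudogenes Rpl34-ps1 and Glns-ps1 and the antisense gene Hoxb3os also fell, with values that reads from similar or overlapping genes make uncertain. Plac9b has a near-identical neighbour, Plac9a.

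Some immune genes changed in YSGr. Camera called no list of immune cells, MHC class I or class II antigen presentation, interferon response, chemokines, complement or immune checkpoints, with adjusted p between 0.157 and 0.96. Of 6 dendritic cell markers Zbtb46 and Flt3 rose, and fry called that list (adjusted p = 0.00567). Of 17 activated microglia and macrophage genes Clec7a, a pattern recognition receptor gene, rose by 2.02 log2 units (SE 0.40) and Gpnmb by 2.00 (SE 0.44), and 15 were not called. The interferon-induced gene Rsad2 fell by 2.11 (SE 0.31) and Ifit2 fell by 1.22 (SE 0.28), and Cd276, an immune checkpoint gene, fell by 0.56 (SE 0.15). Of the T cell and cytotoxic lists only Cd4 and Eomes had enough signal to be tested, and neither was called in YSGr against SG. The complement list had a median of -0.01 and a mean of 0.19, and the mural cell and fibroblast list a median of -0.03 and a mean of 0.04, with the test above 0 in both and neither called (adjusted p = 0.656 and 0.956).

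The number of called genes depended on single libraries. It was 328, 345 and 417 without SG replicates 1, 2 and 3, 400 and 359 without YSGr replicates 1 and 2, and 4257 without YSGr replicate 3. In all, 7556 genes were called with YSGr replicate 3 and YSGnr replicate 1 both left out. Without YSGr replicate 3, 2198 genes were higher and 2059 lower, and without both 3577 and 3979. Of the 78 genes named and called in this comparison, 22 were called in all 9 fits that left out 1 library, among them Gabrd, Cbln3, Gabra6, Slc17a7, Mag, Olig3 and Cenpe. The neural stem cell and erythrocyte lists were not called without YSGr replicate 3 (adjusted p = 0.0546 and 0.162), nor was the erythrocyte list without SG replicate 3 or with the stricter filter (adjusted p = 0.0518 and 0.061).

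**Figure D2:**
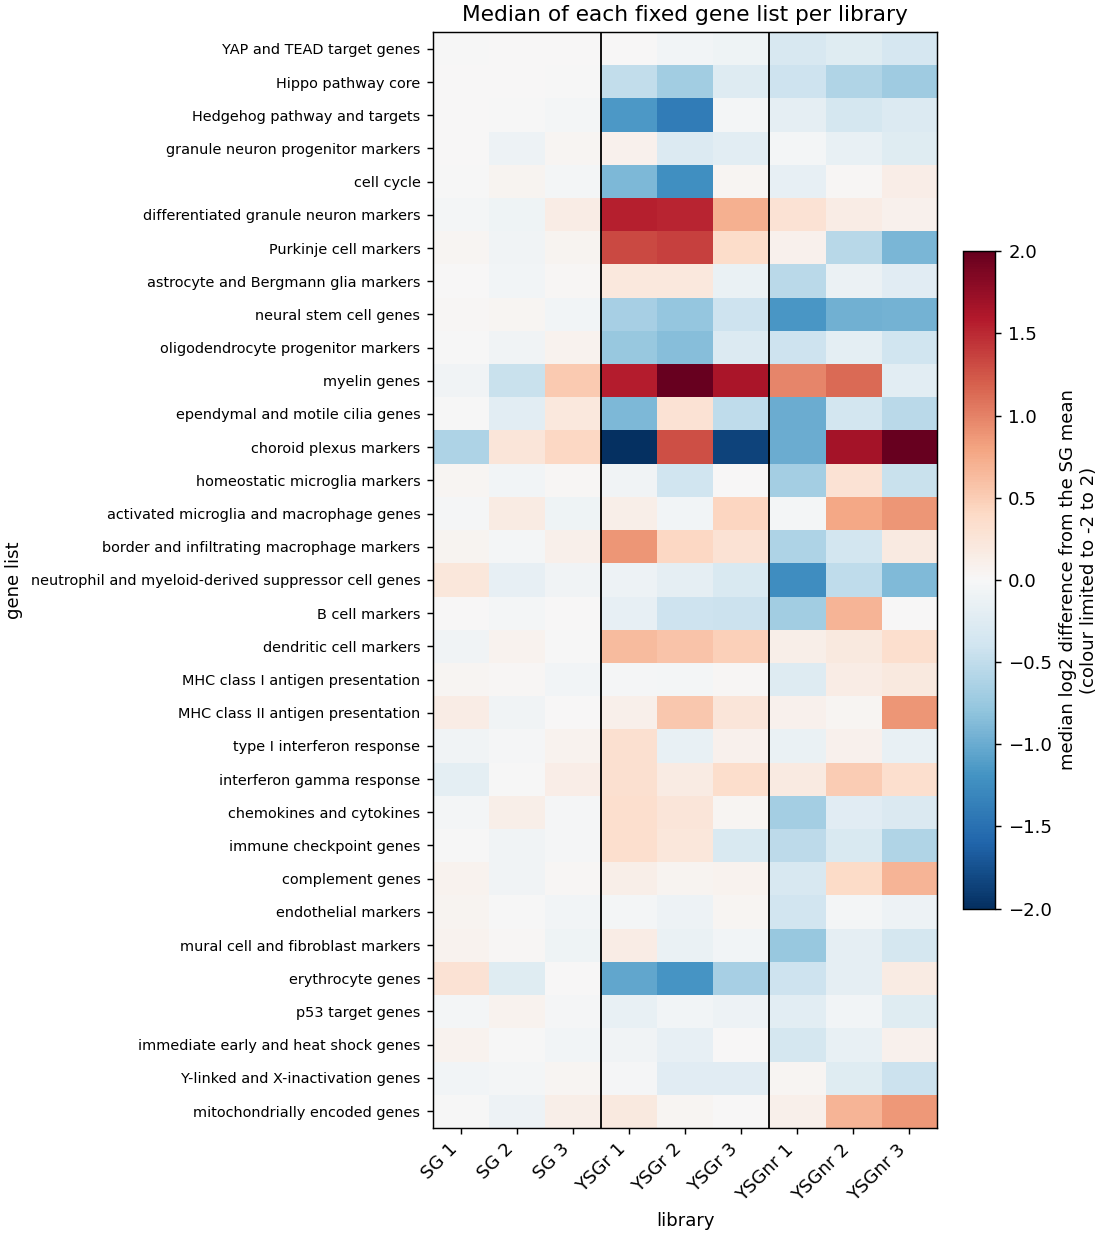
Median over the members of each fixed gene list of the log2 difference from the SG mean, for each of the 9 libraries, with colours limited to -2 and 2. The granule neuron, Purkinje and myelin lists stand above SG in the 3 YSGr libraries, and the cell cycle and Hedgehog medians of YSGr replicate 3 lie at 0.04 and -0.04.

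The comparison of YSGnr with SG asks the same of tumours marked as non-rescued. Of 12 neural stem cell genes 4 fell in YSGnr: Hes5 fell by 1.66 log2 units (SE 0.22, adjusted p = 0.0108), the receptor gene Notch1 fell by 1.64 (SE 0.32, adjusted p = 0.0329), Nes fell by 1.61 (SE 0.29, adjusted p = 0.0257) and Sox2 fell by 1.42 (SE 0.17, adjusted p = 0.00887). Of 14 endothelial markers 3 fell, and of 20 markers of mature granule neurons 5 rose. In all, 181 genes were higher and 331 lower, and 83 and 152 of these differed by at least 2-fold (limma, 15251 tested). The groups did not overlap at 38.2% of the tested genes, against 10% by chance.

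Of the neural stem cell genes 9 fell adjusted over the list alone, and all 12 had values below SG. This list was called at adjusted p = 4.21e-06 and was the only one called with an estimated correlation (adjusted p = 0.0469). Of 15 Hippo pathway core genes Tead1 (log2 fold change -1.34, SE 0.21), Amot (-1.17, SE 0.24) and Wwtr1 (-1.04, SE 0.14) fell, and 7 fell adjusted over the list alone. The list was called at adjusted p = 0.00186, and at adjusted p = 0.205 with an estimated correlation. The YAP and TEAD target list was not called by camera (adjusted p = 0.153) and was called lower by fry (adjusted p = 0.00941): Nt5e rose, Ajuba and Asap1 fell, and 7 genes fell and 3 rose adjusted over the list alone. Of 30 cell cycle genes Cenpe fell and 29 were not called, and of 16 Hedgehog genes Gli3 fell by 1.13 (SE 0.16) and 15 were not called.

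Of 20 differentiated granule neuron markers 5 rose, or 7 adjusted over the list alone, including Gabrd (4.89-fold, adjusted p = 0.00547), Cbln3 (3.24-fold, adjusted p = 0.00438) and Gabra6 (2.77-fold, adjusted p = 0.0227). Of 12 myelin genes Opalin (7.83-fold) and Cnp (1.83-fold) rose, and 5 rose adjusted over the list alone. Of 17 activated microglia and macrophage genes Clec7a rose by 1.84 log2 units (SE 0.40), of 11 ependymal genes Rfx2 fell by 0.88 (SE 0.19), and of 10 mitochondrially encoded genes none was called while all 10 had values above SG, a direction that the list test turned under quantile normalization (adjusted p = 0.29). These 5 lists were called at adjusted p = 0.0388, 0.0092, 0.0092, 0.0388 and 0.0291, and with an estimated correlation the adjusted p was 0.689, 0.637, 0.663, 0.593 and 0.637. By fry none of the 5 was called (adjusted p = 0.217, 0.217, 0.263, 0.124 and 0.124). The granule neuron list was not called without SG replicate 2, YSGr replicate 3 or YSGnr replicate 1 (adjusted p = 0.0883, 0.121 and 0.265), nor the myelin list without SG replicate 2 or YSGnr replicate 1 (adjusted p = 0.0596 and 0.251). The ependymal list was not called without SG replicate 3, YSGr replicate 3 or YSGnr replicate 1 (adjusted p = 0.0707, 0.0888 and 0.242), the microglia list without YSGnr replicate 2 or 3 (adjusted p = 0.0583 and 0.0593), and the mitochondrial list without SG replicate 2, YSGr replicate 3 or YSGnr replicate 3 (adjusted p = 0.0883, 0.0653 and 0.0593). The granule neuron list was also lost with median scaling, quantile normalization and the replicate block (adjusted p = 0.0542, 0.108 and 0.0735), the microglia list with quantile normalization (adjusted p = 0.0623), and the mitochondrial list with the block (adjusted p = 0.0562). The ependymal list was lost with no filter, the stricter filter, quantile normalization and the length and GC trend removed (adjusted p = 0.101, 0.124, 0.096 and 0.109). In the same group the differences from SG followed transcript length, with a Spearman rho over genes of -0.65 and -0.62 in YSGnr replicates 2 and 3 and -0.08 in replicate 1. With a length and GC trend removed, 73.3% of the genes called in YSGnr against SG kept call and direction. This share was taken over the 494 called genes with a length and GC value. The others lost the call, so part of the calls in this comparison depended on that trend.

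Of 14 endothelial markers 3 fell: Flt1 (log2 fold change -1.38, SE 0.21) and Kdr (-1.37, SE 0.19), both VEGF receptor genes, and the cadherin gene Cdh5 (-0.95, SE 0.17). Of 16 mural cell and fibroblast markers the fibronectin gene Fn1 fell by 1.44 (SE 0.29) and Pdgfrb fell by 0.95 (SE 0.15). Camera called neither list (adjusted p = 0.114 and 0.159), and fry called the endothelial list (adjusted p = 0.0454). Among immune genes the chemokine gene Cxcl16 rose by 1.75 log2 units (SE 0.38) and Serping1, a complement inhibitor gene, by 1.01 (SE 0.20), and Mmp9 fell by 1.78 (SE 0.39). Camera called no list of MHC, interferon response or immune checkpoint genes, with adjusted p between 0.166 and 0.702. The neutrophil and myeloid-derived suppressor cell list, with 1 of 5 genes called, was not called by camera (adjusted p = 0.11) and was called lower by fry (adjusted p = 0.00576). The Purkinje cell list, not called (adjusted p = 0.945), had a median of -0.56 and a mean of -0.10 with a camera direction above 0. Median, mean and test also differed in sign for the cell cycle and B cell lists (adjusted p = 0.727 and 0.998).

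Among the genes that the naming rule admits, the largest increases outside the lists were Plac9b (6.53-fold) and Plac9a (6.08-fold), Klhdc9 (4.70-fold), Hsd11b1, a glucocorticoid-activating enzyme gene (4.49-fold), and Fam107a (4.47-fold). The largest decreases among them were the chemokine gene Ccl21a (log2 fold change -4.85, SE 0.50), Glns-ps1 (-4.63), Pdlim3 (-3.48, SE 0.43), the homeobox gene Meis2 (-3.34, SE 0.58), Ddn (-3.00), Crym (-2.87) and AA465934 (-2.78). Predicted-gene symbols, which the rule leaves out, include a larger fall, that of Gm26825. Ccl21a belongs to a cluster of near-identical genes and its value is uncertain.

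Without SG replicates 1, 2 and 3 there were 19, 23 and 23 called genes, without YSGr replicates 1, 2 and 3 there were 236, 225 and 2634, without YSGnr replicates 1, 2 and 3 there were 3332, 208 and 82, and with YSGr replicate 3 and YSGnr replicate 1 both left out 8074. The sets without YSGnr replicate 1 (1613 higher and 1719 lower) and without both (4061 and 4013) were nearly even in direction. Of the 55 genes named and called, Plac9b, Gabrd, Ccl21a, AA465934 and Cbln3 were called in all 9 fits that left out 1 library.

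In both comparisons with SG, 120 genes were higher and 140 lower, 260 in all, and none was called in opposite directions. Independent lists of these sizes would share 25.0. The log2 fold changes correlated across genes at 0.44 with a covariance of 0.20, and 59.7% of genes had the same sign. A simulation of unchanged groups gave 0.50, 0.08 and 66.7%. It gave all libraries of a gene the same spread, which sets the correlation and the same-sign share in advance. The SG pairs correlated at 0.986 to 0.992, against values down to 0.929 in YSGr and 0.923 in YSGnr. The simulated values therefore do not show what shared controls alone would give here. Genes are not independent replicates. The 3 SG libraries cannot be split into parts of at least 2 libraries each, so part of the excess over independent lists may come from the shared controls. Without SG replicates 1, 2 and 3 the overlap was 17, 18 and 19 genes, without YSGr replicates 1, 2 and 3 it was 99, 86 and 714, and without YSGnr replicates 1, 2 and 3 it was 756, 139 and 66.

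The comparison of YSGr with YSGnr asks what separates rescued from non-rescued tumours of the same labelled genotype. All YSGr libraries had high Xist, and YSGnr replicates 2 and 3 had high Y-linked transcripts instead. Only YSGnr replicate 1, the library with the fewest reads, was like YSGr in these transcripts. Differences between these groups therefore cannot be told apart from the sex of the animals. Neuronal genes were higher in YSGr: of 12 Purkinje cell markers 10 rose, or 12 adjusted over the list alone, including Gad2 (3.37-fold, adjusted p = 0.0403) and Calb1 (3.17-fold, adjusted p = 0.0297). Of 20 differentiated granule neuron markers 13 rose, or 16 adjusted over the list alone, including Vsnl1 (3.35-fold, adjusted p = 0.0278) and Cbln3 (3.09-fold, adjusted p = 0.0158). With all 9 libraries in the fit 776 genes were higher and 134 lower in YSGr, and 505 and 59 differed by at least 2-fold (limma, 15251 tested). With the 6 libraries of these groups alone limma called no gene, with 3368 at an unadjusted p under 0.05, so all 910 calls needed the SG libraries in the estimate of spread. By voom on back-calculated reads of all 9 libraries 1800 genes were called. The share of calls that were higher in YSGr was 85.3% in the main fit and 82.9% with median scaling. It was 72.9% by voom and 68.8% with a length and GC trend removed.

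Of 30 cell cycle genes none was called over all genes, 21 fell adjusted over the list alone and all 30 had values below YSGnr. Of 18 astrocyte and Bergmann glia markers 3 rose, Gdf10 by 1.05 log2 units (SE 0.18), Hopx by 0.74 (SE 0.14) and Ttyh1 by 0.72 (SE 0.15), and 7 rose adjusted over the list alone. Of 12 myelin genes none was called and 7 rose adjusted over the list alone. Of 12 choroid plexus markers none was called and all 12 had values below YSGnr. Camera called the granule neuron, Purkinje, cell cycle, glia, myelin and choroid plexus lists at adjusted p = 4.57e-09, 5.5e-08, 1.46e-08, 0.00181, 0.00181 and 0.00643, and with an estimated correlation the adjusted p was 0.545, 0.545, 0.545, 0.545, 0.556 and 0.579. By fry the cell cycle, myelin and choroid plexus lists were not called (adjusted p = 0.0878, 0.0978 and 0.196). The lists were not tested on the YSGr and YSGnr libraries alone, where no gene was called. The choroid plexus median relative to SG was -2.61, 1.29 and -1.85 in YSGr replicates 1, 2 and 3 and 1.67 and 2.16 in YSGnr replicates 2 and 3, with YSGnr replicate 1 below 0.

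Kdr rose by 1.15 log2 units (SE 0.19), Flt1 by 0.99 (SE 0.21) and Cdh5 by 0.90 (SE 0.17) among 14 endothelial markers, and Col1a1 by 1.91 (SE 0.37) among 16 mural cell and fibroblast markers; camera called neither list (adjusted p = 0.133 and 0.173), and fry called the endothelial list (adjusted p = 0.0461). Of 22 YAP and TEAD target genes Ptpn14 rose, with a value just below 0 once a length and GC trend was removed and YSGnr replicate 1 left out, and the list was called higher by fry (adjusted p = 0.0171) and not by camera (adjusted p = 0.304). Fry also called the neural stem cell, chemokine, neutrophil, border macrophage and dendritic cell lists higher (adjusted p = 0.0171, 0.0365, 0.0375, 0.0461 and 0.0461). Camera called none of these lists (adjusted p = 0.133, 0.0798, 0.308, 0.0852 and 0.626). The chemokine gene Cxcl12 rose by 0.79 (SE 0.17), the checkpoint receptor gene Sirpa rose by 0.83 (SE 0.16), and Ifit2 fell by 1.17 (SE 0.28). Eomes rose by 1.35 (SE 0.31). It was the 1 gene in the data out of 13 on the cytotoxic and natural killer cell list, so its rise cannot speak for that list or those cells. Cd274, which encodes PD-L1, had a log2 difference of -1.16 (SE 0.52) and was not called (adjusted p = 0.148). Median, mean and test differed in sign for 8 uncalled lists: granule neuron progenitor, B cell, MHC class I, type I interferon, interferon gamma, complement, p53 target and immediate early genes (adjusted p between 0.729 and 0.99). Among the largest differences Rassf6 (7.59-fold), Slc22a6 (6.95-fold), Shh (5.51-fold), Nos1 (5.42-fold) and Skor2 (5.20-fold) were higher in YSGr, Olig3 fell by 3.46 (SE 0.38, adjusted p = 0.0158), and Cybb, an NADPH oxidase gene of phagocytes, fell by 2.13 (SE 0.35). None of the 59 genes named and called in this comparison was called in all 9 fits that left out 1 library.

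The number of called genes was 8, 9 and 10 without SG replicates 1, 2 and 3, 4, 1 and 6528 without YSGr replicates 1, 2 and 3, 4725, 1 and 2 without YSGnr replicates 1, 2 and 3, and 9867 with YSGr replicate 3 and YSGnr replicate 1 both left out. The larger sets were nearly even in direction: 3387 were higher and 3141 lower without YSGr replicate 3, 2556 and 2169 without YSGnr replicate 1, and 4873 and 4994 without both. With median scaling 316 were called, and without YSGnr replicate 1 the glia list and without YSGr replicate 3 the choroid plexus list were not called (adjusted p = 0.115 and 0.258).

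**Figure D3:**
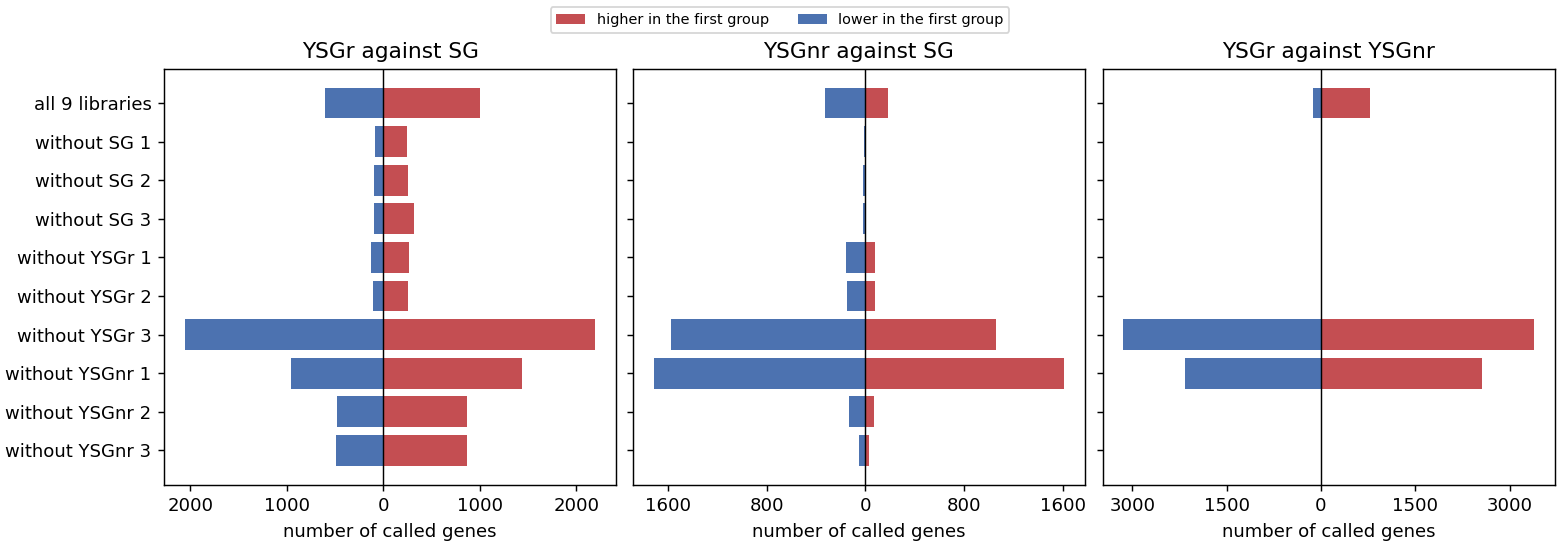
Number of genes called higher (right) and lower (left) in the first group of each comparison, with all 9 libraries and with each library left out; each panel has its own horizontal scale. YSGr against YSGnr goes from 910 called genes to between 1 and 10 when any library other than YSGr replicate 3 or YSGnr replicate 1 is left out, and to 6528 or 4725 without one of these.

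**Figure D4:**
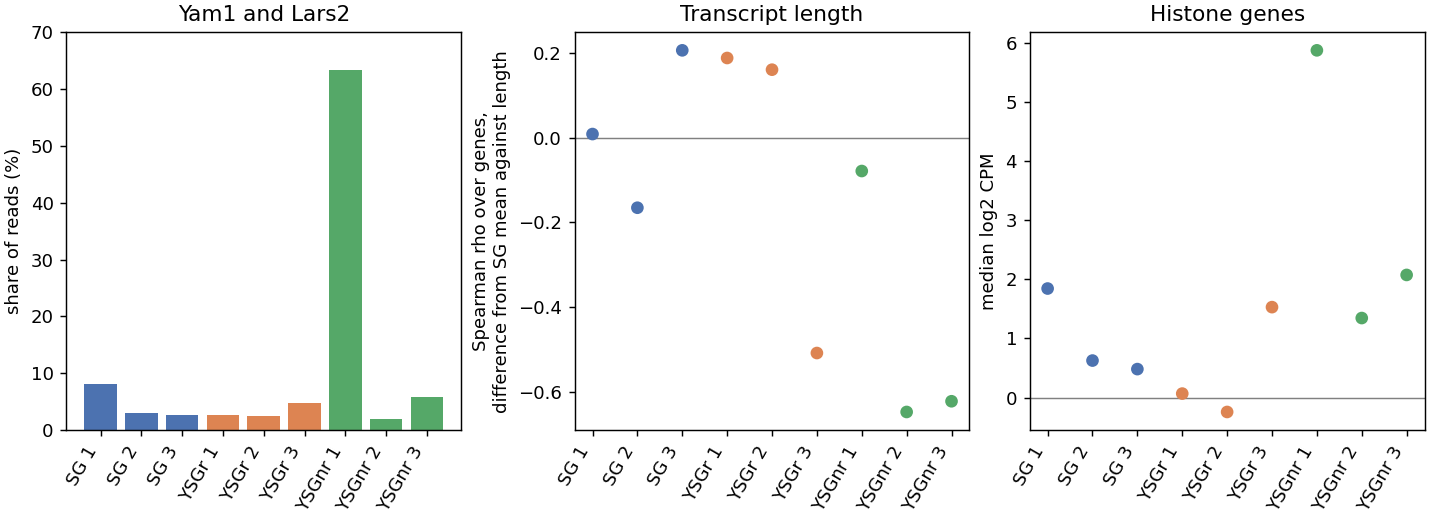
Share of reads in Yam1 and Lars2 (percent), Spearman rho over genes between transcript length and the difference from the SG mean, and median log2 CPM of 38 histone genes, for each library, coloured by group. YSGnr replicate 1 has 63.4% of its reads in Yam1 and Lars2, and YSGr replicate 3 and YSGnr replicates 2 and 3 have rho of -0.51, -0.65 and -0.62.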

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

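The removal of a length and GC trend, the joint omission of YSGr replicate 3 and YSGnr replicate 1, the trend removal without YSGnr replicate 1, voom and the block with the trend removed were chosen after the data were seen; the others were planned. Causes were not tested except where fewer libraries or genes entered by construction. For genes called in YSGr against SG (1608), array weights gave 9661, the joint omission 7556 and the trend removal without YSGnr replicate 1 2750, with 328 to 4257 over single left-out libraries. For YSGnr against SG (512), array weights gave 7316, the joint omission 8074, the trend removal without YSGnr replicate 1 1935, voom 852, the 6 libraries alone 1190 and the replicate block 341, with 19 to 3332 over left-out libraries. For YSGr against YSGnr (910), median scaling gave 316, no trend 568, array weights 9967, the trend removal 1667, the joint omission 9867, the trend removal without YSGnr replicate 1 3762, the replicate block with the trend removed 1451, voom 1800 and the 6 libraries alone 0, where 3368 genes had an unadjusted p under 0.05; left-out libraries gave 1 to 6528. The overlap of both comparisons with SG (260) was 2213 with array weights, 163 with the replicate block, 1857 with the joint omission, 656 with the trend removal without YSGnr replicate 1, 163 with the replicate block and the trend removed and 397 with the 6 libraries alone, and 17 to 756 over left-out libraries. Array weights set YSGr replicate 3 and YSGnr replicate 1 to 0.10 and 0.12 and their estimation did not converge. Gene lists called in YSGr against SG went from 8 to 0 with an estimated correlation, with 6 to 10 over left-out libraries. In YSGnr against SG they went from 7 to 1 with an estimated correlation, 3 with quantile normalization, 11 with the trend removed and 4 with the joint omission, and 4 to 9 over left-out libraries; the mitochondrially encoded genes list turned from higher to lower under quantile normalization, where it was not called (adjusted p = 0.29). In YSGr against YSGnr they went from 6 to 0 with an estimated correlation and 10 with fry, which did not call 3 of these 6, and 6 to 10 over left-out libraries. The list tests were not rerun with the pseudocount, no trend, robust empirical Bayes, array weights or voom. Nor were they rerun with the 6 libraries alone or the replicate block with the trend removed. Yap1 in YSGr against YSGnr was called at 1.86 with array weights and 1.59 with the joint omission, with 0.60 to 1.42 over left-out libraries; over left-out libraries it ran from -2.01 to -1.19 in YSGr and from -2.78 to -2.38 in YSGnr against SG, and array weights gave -0.80 in YSGr against SG. The Ptpn14 log2 fold change, YSGr against YSGnr, turned from above 0 to -0.0018 with the trend removed without YSGnr replicate 1. The replicate numbers did not pair the libraries: 4 of 9 same-number pairs had deviations correlated over 0.1, the range was -0.23 to 0.24, and 1 of 9 libraries correlated best with its own number in both other groups. With the joint omission the granule neuron, myelin and ependymal lists in YSGnr against SG (adjusted p = 0.702, 0.354 and 0.285), the erythrocyte list in YSGr against SG (0.228) and the glia, myelin and choroid plexus lists in YSGr against YSGnr (0.0739, 0.0739 and 0.099) were not called. With the trend removed without YSGnr replicate 1 the same 3 lists in YSGnr against SG (0.115, 0.207 and 0.406) and the glia list in YSGr against YSGnr (0.0631) were not called. Over the called lists, 329 comparisons with an alternative kept direction and call and 69 lost the call, and over the named genes 5164 kept both, 1183 lost the call, 256 gained it and 15 uncalled values changed sign. The depth of YSGnr replicate 1, with 3.53 M reads outside Yam1 and Lars2, limits what can be seen of low genes.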

Other observations

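The tests of histone genes and of sex in this part were chosen only after their results were seen. Of 8 oligodendrocyte progenitor markers 4 fell in YSGr against SG, among them the transcription factor genes Olig1 (log2 fold change -1.22, SE 0.29) and Olig2 (-1.22, SE 0.28), and 3 rose and 5 fell adjusted over the list alone. This list was not called by camera (adjusted p = 0.299) and was called by fry (adjusted p = 0.0126). Of 18 astrocyte and Bergmann glia markers 3 rose in the same comparison, Gfap by 1.71 log2 units (SE 0.37), Hopx by 1.42 (SE 0.14) and Aldoc by 1.06 (SE 0.22), with the list not called by camera (adjusted p = 0.157) or fry (adjusted p = 0.143). The immediate early gene Egr1 fell by 2.13 (SE 0.35) in YSGr and fell by 1.73 (SE 0.35) in YSGnr against SG, and the heat shock gene Hspb1 rose in YSGr against SG by 1.18 log2 units (SE 0.17). Of 6 dendritic cell markers Zbtb46 (log2 fold change 1.48, SE 0.32) and Flt3 (0.83, SE 0.21) rose in YSGr against SG.

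Choroid plexus transcripts varied within groups. Ttr, the transthyretin gene, stood at 7.33, 9.12 and 8.90 log2 CPM in SG, at -1.01, 9.86 and -0.19 in YSGr and at 5.35, 10.13 and 10.51 in YSGnr, and it was called in no comparison; it was chosen after its values were seen. The 3 transcripts that follow were chosen after their values were seen. Gm26825, annotated as a lincRNA on chromosome 5 (5781530 to 5783636), stood between 8.62 and 8.69 log2 CPM in SG and between -3.52 and 0.34 in the other 6 libraries, and the processed pseudogene Gm9855 on chromosome 10 (42054113 to 42055306) between 6.47 and 6.55 and between -3.52 and 0.40. Rpl34-ps1 on chromosome 6 (71124610 to 71124963) stood between 6.14 and 6.29 in SG, at 5.95 and 7.56 in YSGnr replicates 1 and 2, and between -3.52 and -2.37 in the other 4.

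YSGr replicate 3 lay apart from YSGr replicates 1 and 2: Gli1 stood at 7.57 log2 CPM against 5.12 and 5.01, and Atoh1 at 6.89 against 3.89 and 3.34, genes chosen after their values were seen. A transcript length and GC trend in this library accounted for 23.9% of the variance over genes of its difference from replicates 1 and 2, below the 50% set for it as the main source. This share was taken over the 11768 genes with a mean log2 CPM of at least 2 and a length value. A difference between animals of the group was not tested. For an exchange of labels with YSGnr replicate 1, an axis ran from YSGnr replicates 2 and 3 (0) to YSGr replicates 1 and 2 (1). The length and GC trend was removed from each library before the positions were taken. YSGnr replicate 1 lay at 0.32 and held-out YSGr libraries at 0.91 and 0.99, which argues against the exchange. Another value goes with it: the split that equals the exchange called 5858 genes, against 910 for the labels. That split was made with the length and GC trend left in. It also sets together YSGr replicate 3 and YSGnr replicates 2 and 3, which share a length trend. The exchange is therefore not settled. Xist and Ddx3y cannot decide on it, since both libraries had high Xist and Ddx3y at the lowest value, and an exchange would leave this pattern unchanged. A single wrong label on YSGr replicate 3 stays open: the library lay at 0.31, between the bounds set and near the SG libraries at 0.24 to 0.30. Across genes, with the trend left in, it correlated with YSGnr replicates 2 and 3 at 0.966 and 0.960. The values were 0.948 to 0.950 with SG and 0.936 and 0.929 with its own group. YSGr replicate 3 shared the length trend of YSGnr replicates 2 and 3 (Spearman rho -0.51, -0.65 and -0.62), against 0.19 and 0.16 in YSGr replicates 1 and 2. YSGr replicate 3 may correlate with them for that reason, so these correlations cannot decide on its label. Its Xist level of 9.81 with Ddx3y at the lowest value was as in YSGr replicates 1 and 2 and unlike SG and YSGnr replicates 2 and 3. Its Yap1 level of 2.79 lay below the SG mean of 5.06. These values argue against an SG origin. They cannot decide on a YSGnr origin, since YSGnr replicate 1 also had high Xist, Ddx3y at the lowest value and Yap1 at 2.79.

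YSGnr replicate 1 lay apart from YSGnr replicates 2 and 3. Counting noise from the few reads left beside Yam1 and Lars2 would give 7.43% of the variance over genes of its difference from them, and a transcript length and GC trend in replicates 2 and 3 accounted for 30.1%, both below the 50% set. Both shares were taken over the 11768 genes with a mean log2 CPM of at least 2 and a length value. They leave out lower genes, where counting noise is larger, and cannot speak for them. RNA without a poly(A) tail kept in this library remains a candidate explanation, since the histone genes, whose transcripts mostly lack such a tail, had a median 3.80 log2 units above the highest of the other 8 libraries. The library also differed from replicates 2 and 3 in Xist and the Y-linked genes, which the labels do not address, and no biological explanation was tested.

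The genes called in YSGr against SG are not explained by a transcript length and GC trend alone, since 80.9% of those with a length and GC value were called in the same direction once it was removed. The sex of the animals cannot be told apart from the group, because all SG libraries had high Y-linked transcripts and all YSGr libraries high Xist. X-linked genes were called at 10.3%, against 10.6% of autosomal genes. These shares cannot decide on sex, since the groups held no libraries alike in these transcripts. Without YSGnr replicate 1, YSGnr and SG libraries alike had high Y-linked transcripts, and 3332 genes were called between them, or 1935 with the length and GC trend removed.

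The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. For YSGr against SG the real split gave 1608 genes and the highest other 0 (1 of 10 as large), and 8 lists against 9 (2 of 10). For YSGnr against SG it gave 512 genes against 0 (1 of 10), and 7 lists against 9 (4 of 10). For YSGr against YSGnr it gave 910 genes against 5858 (2 of 10), and 6 lists against 9 (7 of 10). The split with 5858 genes sets YSGr replicates 1 and 2 with YSGnr replicate 1 against YSGr replicate 3 with YSGnr replicates 2 and 3. It equals an exchange of the labels of YSGr replicate 3 and YSGnr replicate 1, and it points to a structure of the libraries other than the labels. The libraries of its second side were also those that followed transcript length most, with a Spearman rho of -0.51, -0.65 and -0.62. In the others rho lay between -0.17 and 0.21. The splits were not rerun with the length and GC trend removed, so the count cannot tell an exchange of labels from this trend. For the overlap of 260 genes, 2 of 100 assignments of the 9 libraries, the real one included, gave as many. This does not exclude a chance assignment. Assignments that mix SG with the other groups put the difference of SG into the spread, which nearly fixes a low overlap in advance. The highest other, 1414, took YSGr replicate 3 and YSGnr replicates 2 and 3 as the common control. These are the same 3 libraries that the split with 5858 genes set together.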
